A study of Mus musculus with 22 samples.

How the data were processed

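The series measured mRNA by RNA sequencing in the striatum of mice that carry an EGFP fusion of the ribosomal protein Rpl10a in neurons expressing the dopamine receptor Drd1. Per the labels' protocols, striata of 6 wild-type and 5 Fmr1 mutant animals were homogenised in cycloheximide, nuclei and insoluble membranes were spun out, and tagged ribosomes were pulled down with antibodies against EGFP. A part of the cleared lysate was kept as input. The labels call the pulldown IP and the input Total, and the mutant KO. Per the same protocols, libraries were made with a kit that does not mark the strand, sequenced as paired-end reads, and all pulldowns and sequencing were done in a single batch. The labels give no litter, cage, age or strain.

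The authors deposited raw counts per gene symbol for the 22 libraries, made with STAR and featureCounts on the mm10 genome per the submitters' processing notes, which give no versions. The counts were whole numbers for 55341 genes, and all 55341 symbols were found in GENCODE vM21 (GRCm38/mm10), which supplied gene positions, types, exon lengths and overlaps. The authors also deposited a table of mutant against wild type for each assay, with DESeq2 named in the submitters' processing notes. Per the file headers these tables hold log2 fold changes, p-values and adjusted p-values, 2 columns of mean signal in them were not used, and the log2 values were wild type over mutant, as the sign of Fmr1 shows. All fold changes below were recomputed from the deposited counts, as mutant over wild type or IP over input, and the deposited tables were used only where the text names them.

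The following choices were made before the data were examined: the groups, the 5 comparisons, the tests, the gene lists, the rule for named genes and most alternatives. Mutant against wild type was fitted in the 11 IP libraries and in the 11 input libraries separately. IP against input in each genotype, and the genotype by assay interaction, were fitted over all 22 libraries with 4 groups. Each fit used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, robust quasi-likelihood tests and Benjamini-Hochberg adjustment over all genes tested at 0.05. All adjusted p-values for genes come from this edgeR quasi-likelihood test unless another tool is named. Levels are CPM, that is counts relative to library size, scaled by TMM within the libraries of an assay. Some values were instead scaled over all 22 libraries. These are the cortical marker scores of single animals, the levels of Ddx3y, Slc17a7 and Ttr, and the ratio of Fmr1 in IP over input. Log2 CPM used a prior count of 2.

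The text names Fmr1 in every library. In comparisons of genotype it names up to 15 called genes per direction by p, and where fewer than 5 genes passed also the 5 with the smallest p, given as values. For IP against input it names the 10 genes with the largest fold per direction among called genes with a mean CPM of at least 10, and the members of the D1 and D2 lists. For a gene list it names the 2 to 4 members with the smallest p. Predicted genes without a name were counted and not named. Any other gene is said to have been chosen after its values were seen.

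The 38 gene lists were written by hand from general knowledge of the tissue and of Fmr1. Lists of cell types covered D1 and D2 projection neurons, markers shared by both, interneurons, cortical excitatory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, mural cells and fibroblasts, ependyma and choroid plexus, and red blood cells. Lists of function covered FMRP-bound mRNAs, FMRP family and partners, cytosolic and mitochondrial ribosomal proteins, translation factors, the mTOR pathway, the stress responses, heat shock proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the proteasome, RGS proteins, dopamine and cAMP signalling, muscarinic and opioid receptors, group I mGluR signalling, endocannabinoids, glutamate receptors with postsynaptic scaffolds, GABA, potassium channels, synaptic vesicle release, immediate early genes, chromatin regulators, cholesterol synthesis and the interferon response. A further list held sex-linked genes as a check. The list of 197 FMRP-bound mRNAs came from memory of published binding and is not a copy of a published table. The lists overlap in part.

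Lists with at least 5 tested members were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison, 2-sided. Each was tested again with the correlation estimated from the data, and with fry. The mean log2 CPM of a list's members was also taken per library as a score and compared between genotypes by a 2-sided exact permutation test over the 462 ways to divide 6 and 5 animals. The smallest p this test can give is 0.00216.

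The animal numbers pair each IP library with the input of the same lysate, per the labels' protocols. Over 8621 genes, deviations from the group means of all 11 IP libraries correlated best with the input of the same number, with correlations from 0.19 to 0.47 against at most 0.18 for other animals. The comparisons of IP with input were fitted without this pairing, and again with the animal as a block.

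The alternatives were RLE scaling, no filter beyond 1 read, a filter of CPM of at least 1 in at least 5 libraries, DESeq2 1.42.0, limma-voom, each animal left out in turn, all 22 libraries in a single fit, a glial and vascular score as a covariate, and 1 surrogate variable from sva 3.50.0. Leaving out animals 1, 3, 9 and 12, and a cortical marker score as a covariate, were added after the data were seen. Random lists matched on exon length, GC content and expression, and other divisions of the samples, were used for the closing section.

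The fits were tested on simulated counts with known changes. Of simulated changes of 2-fold, 67.2% were recovered for the IP comparison of genotypes, 73.1% for the input comparison and 55.2% for the interaction. Of changes of 1.5-fold, 37.3%, 47.8% and 8.96% were recovered. Of changes of 4-fold, 89.4%, 95.5% and 81.8% were recovered. Unchanged genes gave 4, 10 and 5 false calls. Only genes with a mean CPM of at least 1 were changed, and the simulated counts held no pairing of libraries by animal. Apart from the changed genes they also held no difference between IP and input. The recovery given for the interaction may thus be too high for mRNAs that the pulldown depletes.

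Genes were counted without strand, so reads from overlapping genes on opposite strands cannot be told apart, and counts of near-identical copies, such as ribosomal protein genes with processed pseudogenes, the Ifit family and the alpha-globin genes, are uncertain.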

Results

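Ribosome-bound mRNA of striatal neurons expressing the dopamine receptor Drd1 (D1 neurons) was compared between wild-type mice and mice mutant for Fmr1, a model of fragile X syndrome. Fmr1 encodes FMRP, an RNA-binding protein that associates with ribosomes. Each of 6 wild-type animals (numbers 1, 4, 12, 13, 14 and 20) and 5 mutant animals (2, 3, 9, 10 and 11) gave a library from the pulldown of EGFP-tagged ribosomes (IP) and a library from the input lysate, 22 in all. The series title states the question as how mRNA translation is altered in striatal D1 neurons of Fmr1 model mice. Of the 5 sex-linked genes listed as a check, Xist had at most 4 reads in any library and Ddx3y lay between 72.7 and 120.4 CPM in all 22.

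Total counts per library spanned an 8.79-fold range in IP and a 1.72-fold range in input. Depth did not separate the genotypes by an exact permutation test in IP (p = 0.745) or input (p = 0.180). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 0.420% to 0.904% of the counts in IP and 25.1% to 53.2% in input. Their input share was 31.2% ± 5.07 (SD, n = 6) in wild type and 38.4% ± 9.14 (SD, n = 5) in the mutant. An exact permutation test did not separate the genotypes by this share (p = 0.126), which does not show that the shares are equal. Mutant animal 10 had the highest share, at 53.2%.

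Markers of cortical excitatory neurons, which the striatum largely lacks, set 4 animals apart. The mean log2 CPM of these markers in input was 2.86 to 4.90 in wild-type animals 1 and 12 and mutant animals 3 and 9, and at most 0.72 in the other 7 animals. In IP the same 4 animals had 2.46 to 3.42 and the others at most -0.43. Slc17a7, the vesicular glutamate transporter of cortical neurons, ranged from 0.639 to 91.0 CPM in wild-type input. The score of the markers tested did not differ by genotype in input (exact permutation p = 0.623) or IP (p = 0.660).

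**Figure D1:**
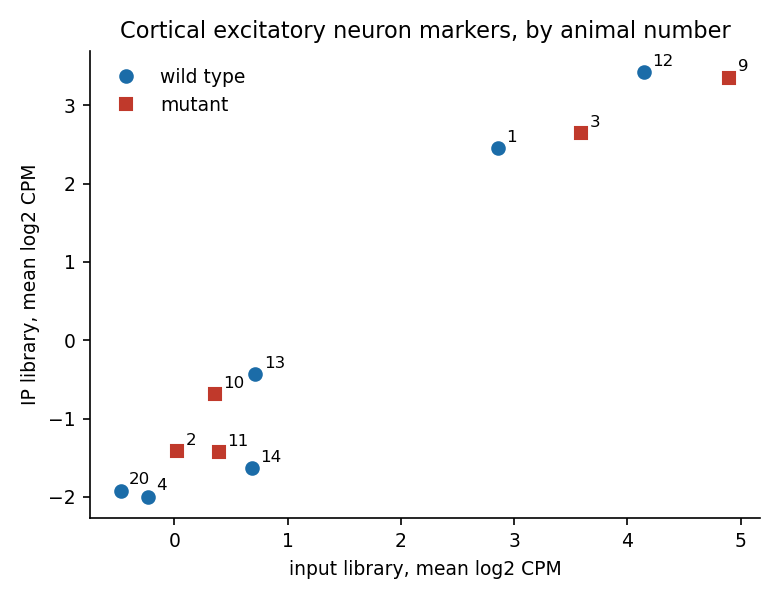
Mean log2 CPM of cortical excitatory neuron markers in the IP library (vertical axis) against the input library (horizontal axis) of each animal, numbered, with wild type as circles and mutant as squares. Animals 1, 3, 9 and 12 lie at 2.86 or above in input, and the other 7 at 0.72 or below.

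Fmr1 itself was measured first. In IP it stood at 99.8 CPM ± 14.8 (SD, n = 6) in wild type and 11.6 CPM ± 1.47 (SD, n = 5) in the mutant, which is 11.6% of the wild-type mean. In input it stood at 55.2 CPM ± 4.36 (SD, n = 6) and 11.4 CPM ± 1.34 (SD, n = 5), which is 20.6%. Every mutant library lay below every wild-type library in both assays (exact permutation p = 0.00216 in each, the smallest that 462 divisions allow), so each library matched its genotype label. The mutant libraries still held 150 to 623 Fmr1 reads in IP and 255 to 542 in input. The gene lies on chromosome X from 68678541 to 68717963 (GRCm38/mm10), and 0.8% of its exon bases overlap another annotated gene.

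IP was compared with input to show which mRNAs the pulldown enriched. The D1 markers rose in IP over input in all 10 of 10 members in both genotypes, with a median log2 fold change of 1.28 in wild type (n = 6) and 1.62 in the mutant (n = 5). Drd1 rose by 1.37 ± 0.11 (SE) in wild type and 1.61 ± 0.12 in the mutant. Chrm4, a muscarinic receptor of D1 neurons, rose by 2.10 ± 0.15 in wild type, and Pdyn, the dynorphin precursor, by 1.30 ± 0.18 in wild type and 1.38 ± 0.19 in the mutant. The smallest D1 changes were those of Zfp521, at 0.57 ± 0.11 and 0.47 ± 0.12. All 7 measured D2 markers fell in both genotypes, with medians of -3.65 and -3.54. Drd2 changed by -3.65 ± 0.15 (SE) in wild type and -3.54 ± 0.16 in the mutant, Adora2a, an adenosine receptor, by -4.72 ± 0.19 and -4.17 ± 0.20, and Penk, the enkephalin precursor, by -4.01 ± 0.22 and -3.74 ± 0.24. Plxdc1 fell least, by 1.38 ± 0.35 and 1.24 ± 0.38.

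Glial and other neuronal markers were also depleted. All 14 oligodendrocyte markers (medians -4.96 in wild type and -5.02 in the mutant), all 14 microglia markers (-5.10 and -5.58), all 12 astrocyte markers (-3.84 and -3.78) and all 8 oligodendrocyte precursor markers (-4.76 and -4.32) fell in both genotypes. Interneuron markers fell in 12 of 13 members in wild type (median -4.69) and 10 of 13 in the mutant (-4.07). The same counts were found when adjusted over the list alone, except for 11 interneuron markers in the mutant. Of 37 lists tested, camera called 23 in each genotype, and fry called 33 in wild type and 30 in the mutant. These 7 cell type lists, D1 and D2 included, were called in both (camera adjusted p from 2.41e-54 to 2.78e-09 in wild type) and kept their calls with an estimated correlation, the highest adjusted p being 0.0132.

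Among other lists, 148 of 197 FMRP-bound mRNAs rose and 17 fell in wild type (152 and 17 adjusted over the list alone), with a median of 0.52, and 136 rose and 23 fell in the mutant (139 and 23), with a median of 0.47. This list's adjusted p was 0.0305 in wild type and 0.0503 in the mutant with an estimated correlation. Among its members, Prkcb, a protein kinase C, rose by 1.82 ± 0.09 (SE) in wild type. FMRP family and partners had medians of 0.42 and 0.40 (adjusted p = 0.0464 and 0.0503 with an estimated correlation), with Cyfip2 at 0.98 ± 0.07 in wild type. Dopamine and cAMP signalling (medians 0.59 and 0.63) and group I mGluR signalling (0.53 and 0.56) were higher in IP in both genotypes, with adjusted p of at most 0.00646 with an estimated correlation. All 12 measured mitochondrially encoded mRNAs fell in IP (adjusted p = 0.0155 and 0.0112 with an estimated correlation). Of cytosolic ribosomal protein mRNAs, 76 of 79 fell in wild type (77 adjusted over the list alone) and 78 in the mutant (79), with medians of -1.05 and -1.21, and adjusted p = 0.113 and 0.0755 with an estimated correlation.

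The other lists called in both genotypes lost their calls with an estimated correlation. These were shared projection neuron markers (median 0.58 in wild type, adjusted p = 0.137 with an estimated correlation), chromatin regulators (0.46, 0.101), synaptic vesicle release (0.44, 0.170), GABA receptors and synthesis (0.39, 0.109), glutamate receptors with postsynaptic scaffolds (0.38, 0.0745), potassium channels (0.31, 0.304), red blood cells (-4.93, 0.0745), interferon response (-2.82, 0.257) and mural cells and fibroblasts (-2.53, 0.119). In the mutant their estimated-correlation p ran from 0.0503 to 0.305. The glutamate receptor and potassium channel lists had negative means in both genotypes (-0.08 and -0.02 in wild type) beside positive medians. The mTOR pathway was called in wild type (median 0.24, mean -0.04, camera adjusted p = 0.0340, and adjusted p = 0.154 with an estimated correlation), and not without animal 13 (0.0579) or among genes with a CPM of at least 1 in at least 5 libraries (median 0.20, 0.0940). The proteasome was called in the mutant (median 0.11, camera adjusted p = 0.0376, and adjusted p = 0.467 with an estimated correlation), and not with the animal as a block (median 0.12, 0.0665), with RLE scaling (0.07, 0.0633), among genes with a CPM of at least 1 in at least 5 libraries (0.08, 0.117) or without animals 1, 3, 9 and 12 (0.09, 0.0757). Not called in wild type were cortical excitatory neurons (median -0.56), endothelium (-1.94), ependyma and choroid plexus (-2.78), mitochondrial ribosomal proteins (-0.15), translation factors (0.03), stress responses (0.01), heat shock proteins (0.04), oxidative phosphorylation (-0.21), RGS proteins (0.11), muscarinic and opioid receptors (0.14), endocannabinoids (-0.01), cholesterol synthesis (-0.44), proteasome subunits (0.10) and immediate early genes (0.53). Means were negative beside positive medians for RGS proteins (-0.25), muscarinic and opioid receptors (-0.68), stress responses (-0.36) and heat shock proteins (-0.40). With the animal as a block, the ependyma and choroid plexus list was called in wild type (camera adjusted p = 0.0307), as were immediate early genes in wild type (0.00119) and the mutant (0.000346).

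**Figure D2:**
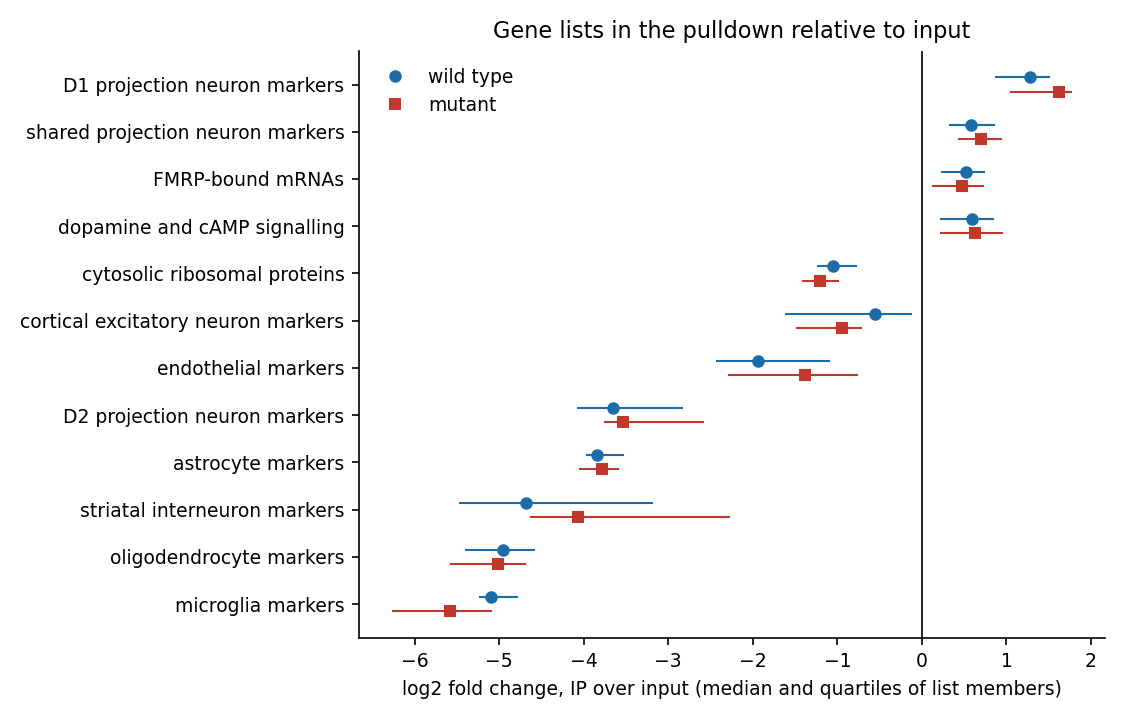
Median (point) and quartiles (line) of the log2 fold change of IP over input for the members of 12 gene lists, with wild type as circles and mutant as squares. D1 markers lie at medians of 1.28 and 1.62, and D2, astrocyte, interneuron, oligodendrocyte and microglia markers below -3.

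By gene, 8585 of 17311 tested differed between IP and input in wild type, with 3779 higher in IP and 4806 lower. In the mutant 8188 differed, with 3610 higher and 4578 lower. Of these, 7007 genes were called in the same direction in both genotypes and 2 in opposite directions. Without animals 1, 3, 9 and 12 the counts were 7941 in wild type and 7298 in the mutant. Tnrc18, a chromatin-associated protein, had the highest fold in both genotypes, at 2.61 ± 0.19 (SE) in wild type and 2.36 ± 0.21 in the mutant. The noncoding RNA Bc1, a small neuronal cytoplasmic RNA, was the most depleted in wild type at -7.22 ± 0.21, followed by Rn7sk, a small nuclear RNA, at -6.74 ± 0.19. Others among the 10 most enriched in both genotypes were Bahcc1, Chrm4, Kalrn, Bcor, Prr12, Nup98 and Prkcb, with Gse1 and Mir6236 in wild type and Isl1 and Ebf1 in the mutant. The most depleted in wild type also held Ptgds, mt-Rnr1, mt-Rnr2, Gjc3, Ctss, Mog, Opalin and Ttr, and Ttyh2, Hbb-bt and mt-Atp6 stood among them in the mutant. The mt-Atp6 fold is not given, since mutant IP libraries held at most 1 read of it. Ttr, a choroid plexus gene, reached 2068 CPM in the input of wild-type animal 20 and lay between 6.52 and 36.6 CPM in that of the other 5 wild-type animals, and its fold was -6.31 ± 1.63. The median over all genes was -0.11 in each genotype. These folds are relative to the TMM scaling of the libraries and do not measure amounts of RNA.

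Mutant and wild type were then compared in the pulldown, which asks which mRNAs differ on D1 ribosomes. In IP, 8 of 14456 genes tested passed, and all 8 were lower in the mutant. Fmr1 fell by 3.10 ± 0.13 (SE) on the log2 scale, which is 8.58-fold lower. Abi3bp, a secreted protein that binds extracellular matrix, stood at 44.1 CPM ± 6.60 (SD, n = 6) in wild type and 15.6 ± 3.56 (SD, n = 5) in the mutant, with a log2 fold change of -1.50 ± 0.16 (SE, adjusted p = 0.000163). Tns1, tensin 1, which links integrin adhesions to actin, fell from 55.3 CPM ± 8.33 to 22.3 ± 4.70 (-1.31 ± 0.14, adjusted p = 0.000163). Igsf9b, an adhesion protein of inhibitory synapses, fell from 64.8 CPM ± 9.46 to 33.8 ± 4.73 (-0.94 ± 0.12, adjusted p = 0.00103).

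The other 4 genes passed by less. Cdh4, a cadherin, stood at 17.4 CPM ± 5.85 in wild type and 5.87 ± 1.79 in the mutant (-1.55 ± 0.25, adjusted p = 0.0211). Pkp4, plakophilin 4 of cell junctions, stood at 159.5 ± 12.3 and 113.4 ± 13.6 (-0.49 ± 0.08, adjusted p = 0.0318). Isg15, an interferon-induced modifier protein, stood at 3.03 ± 1.61 and 0.276 ± 0.201, with 1 to 17 reads in the mutant libraries (-3.50 ± 0.60, adjusted p = 0.0318). Adamts18, a secreted metalloprotease, stood at 1.54 ± 0.291 and 0.192 ± 0.0972, with 2 to 6 reads in the mutant libraries (-3.04 ± 0.53, adjusted p = 0.0318). The genes lie on 7 chromosomes in GRCm38/mm10: Fmr1 on X, Tns1 on 1 (73910231 to 74124449), Cdh4 (179442431 to 179899373) and Pkp4 (59160850 to 59355208) on 2, Isg15 on 4 (156199424 to 156200818), Adamts18 on 8 (113697126 to 113848738), Igsf9b on 9 (27299204 to 27357546) and Abi3bp on 16 (56477878 to 56690135).

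**Figure D3:**
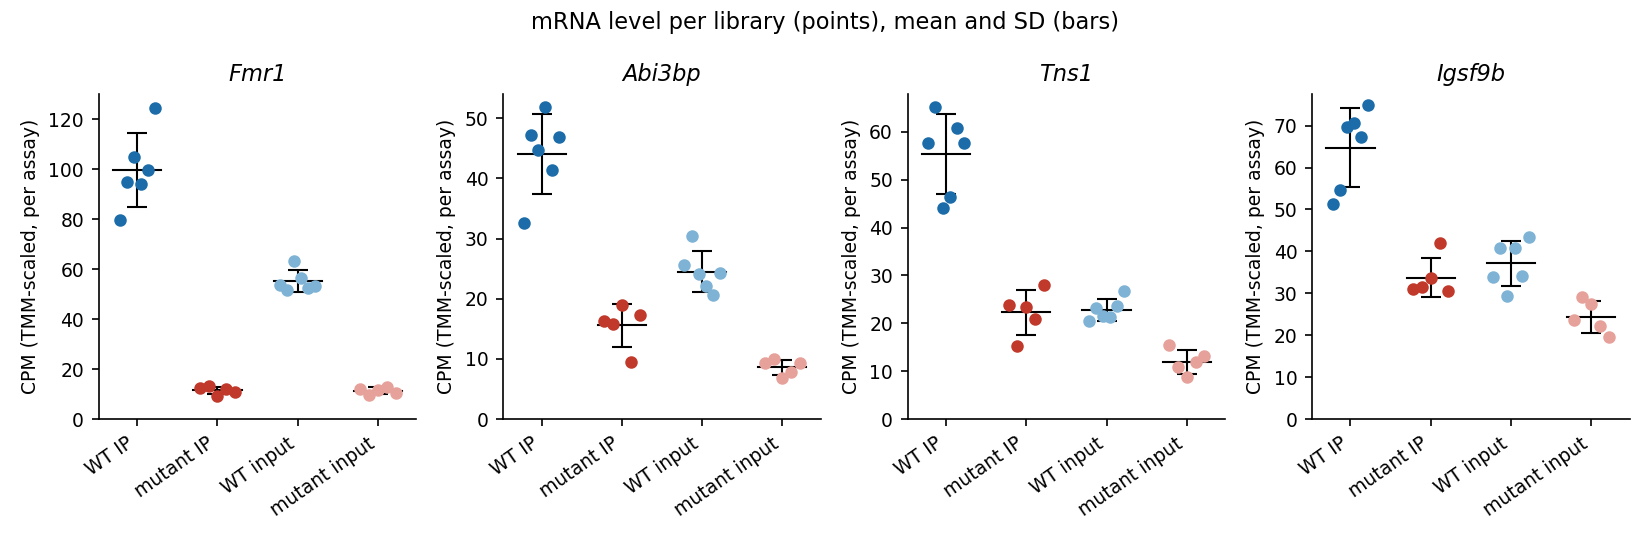
Level in CPM of Fmr1, Abi3bp, Tns1 and Igsf9b in each library (points), with the mean and SD of each group (bars), for wild-type and mutant IP and input. In IP every mutant library lies below every wild-type library for these 4 genes, which were called there.

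Leaving out single animals ended the calls of the last 4 genes but not those of Fmr1, Abi3bp, Tns1 and Igsf9b. The call ended for Cdh4 without animal 3, 4, 9, 10, 11, 12 or 13 (adjusted p up to 0.0736), for Isg15 without 1, 2, 3, 4, 9, 10, 12 or 14 (up to 0.129), for Pkp4 without any but animal 3 (up to 0.145), and for Adamts18 without any but animal 20 (up to 0.1175). The count was 4 without animal 4, 10 or 12 and 5 without animal 2, 3, 9, 11 or 13. Over the 11 leave-outs the log2 fold change ranged from -1.67 to -1.40 for Cdh4, -3.85 to -3.23 for Isg15, -0.55 to -0.45 for Pkp4 and -3.27 to -2.86 for Adamts18. Without animals 1, 3, 9 and 12 the count was 8, of which 5 were shared, with Cdh4 (-1.51), Isg15 (-3.15) and Adamts18 (-3.10) not called, and limma-voom called only the first 4. The authors' deposited DESeq2 table lists 81 genes at an adjusted p under 0.05, 70 lower and 11 higher in the mutant, among them 6 of the 8. Isg15 and Adamts18 have no adjusted p there.

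Lists in IP shifted by small amounts. Of the 197 FMRP-bound mRNAs, which encode large synaptic, cytoskeletal and chromatin proteins, 158 had a negative log2 fold change and 39 a positive one, with a median of -0.11 (camera adjusted p = 1.23e-13, and adjusted p = 0.441 with an estimated correlation). No member passed over all genes tested, and 3 fell when adjusted over the list alone: Med13l, a subunit of the Mediator complex (-0.37 ± 0.08 SE), Ryr2, a calcium release channel (-0.47 ± 0.11), and Iqsec1 (-0.30 ± 0.07). Of nuclear-encoded oxidative phosphorylation mRNAs, 70 of 76 were positive with a median of 0.13 (camera adjusted p = 6.38e-15, and adjusted p = 0.462 with an estimated correlation). None passed over all genes, and Ndufb9 (0.36 ± 0.08), Cox6a1 (0.28 ± 0.07) and Uqcrh (0.35 ± 0.09), subunits of complexes I, IV and III, rose when adjusted over the list alone. Per library, the FMRP-bound score was 7.82 ± 0.07 (SD, n = 6) in wild type and 7.72 ± 0.07 (SD, n = 5) in the mutant (exact permutation p = 0.0455, and 0.432 adjusted over the lists), and the oxidative phosphorylation score gave an exact permutation p of 0.0714.

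None of the 14 lists called in IP kept its call with an estimated correlation, the smallest adjusted p being 0.337 for group I mGluR signalling. Other lists lower in mutant IP by camera at its preset correlation were glutamate receptors with postsynaptic scaffolds (34 of 39 negative, median -0.14, adjusted p = 1.60e-05), group I mGluR signalling (15 of 19, -0.11, 0.000794), interferon response (9 of 12, -0.29, 0.000378), mitochondrially encoded genes (6 of 7, -0.24, 0.00159), chromatin regulators (35 of 43, -0.07, 0.00235), potassium channels (31 of 43, -0.10, 0.0263) and GABA receptors and synthesis (16 of 20, -0.10, 0.0381). Higher were cytosolic ribosomal proteins (62 of 79 positive, 0.09, 0.000289), mitochondrial ribosomal proteins (43 of 51, 0.10, 0.000888), proteasome subunits (22 of 31, 0.06, 0.0224), oligodendrocyte markers (10 of 13, 0.15, 0.0236) and astrocyte markers (8 of 10, 0.38, 0.0460). Isg15 was the only member of these 12 lists to pass over all genes. Adjusted over the list alone, 4 interferon genes fell, Isg15, Ifit1 (-4.19 ± 1.20), Oasl2 and Irf9, and 4 mGluR genes fell, Prkca (-0.38 ± 0.08), Itpr1 (-0.27 ± 0.08), Cyfip2 (-0.19 ± 0.06) and Prkcb (-0.27 ± 0.08). Of lists not called, Rgs14 (-0.54 ± 0.12) and Rgs4 (-0.34 ± 0.09), regulators of G-protein signalling, the D1 marker Zfp521 (-0.53 ± 0.12) and the microglia gene Cx3cr1 (-2.84 ± 0.89) fell when adjusted over the list alone.

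Leaving out an animal ended 7 of these list calls, given with the range of the median over all 11 leave-outs: astrocytes without 3, 4, 9, 11, 12, 14 or 20 (adjusted p up to 0.342, median 0.24 to 0.54), oligodendrocytes without 9, 12 or 20 (up to 0.150, 0.10 to 0.29), cytosolic ribosomal proteins without 3 or 20 (up to 0.0778, 0.04 to 0.16), the proteasome without 2, 11 or 12 (up to 0.0913, 0.03 to 0.08), GABA without 2, 11, 12, 13 or 20 (up to 0.236, -0.12 to -0.06), potassium channels without 2, 11, 12 or 13 (up to 0.317, -0.16 to -0.04) and chromatin regulators without 2, 3 or 20 (up to 0.0709, -0.09 to -0.04). Of the lists that stayed called, medians ranged from -0.62 to -0.10 for the interferon response (adjusted p up to 0.0233), -0.39 to -0.18 for mitochondrially encoded genes (0.0484), 0.09 to 0.16 for mitochondrial ribosomal proteins and -0.16 to -0.09 for glutamate receptors. The number of lists called was 9 without animal 20. Without animals 1, 3, 9 and 12 the FMRP-bound median was -0.14 and the oxidative phosphorylation median 0.20, and the calls of astrocytes (median 0.01 against 0.38, adjusted p = 0.397) and oligodendrocytes (0.16 against 0.15, adjusted p = 0.225) ended. The interferon median was then -0.62. Other settings ended the astrocyte call as well (camera adjusted p up to 0.423). These were no filter beyond 1 read, and the glial and vascular score, 1 surrogate variable or the cortical score as a covariate. The oligodendrocyte call also ended with the glial and vascular score as a covariate.

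**Figure D4:**
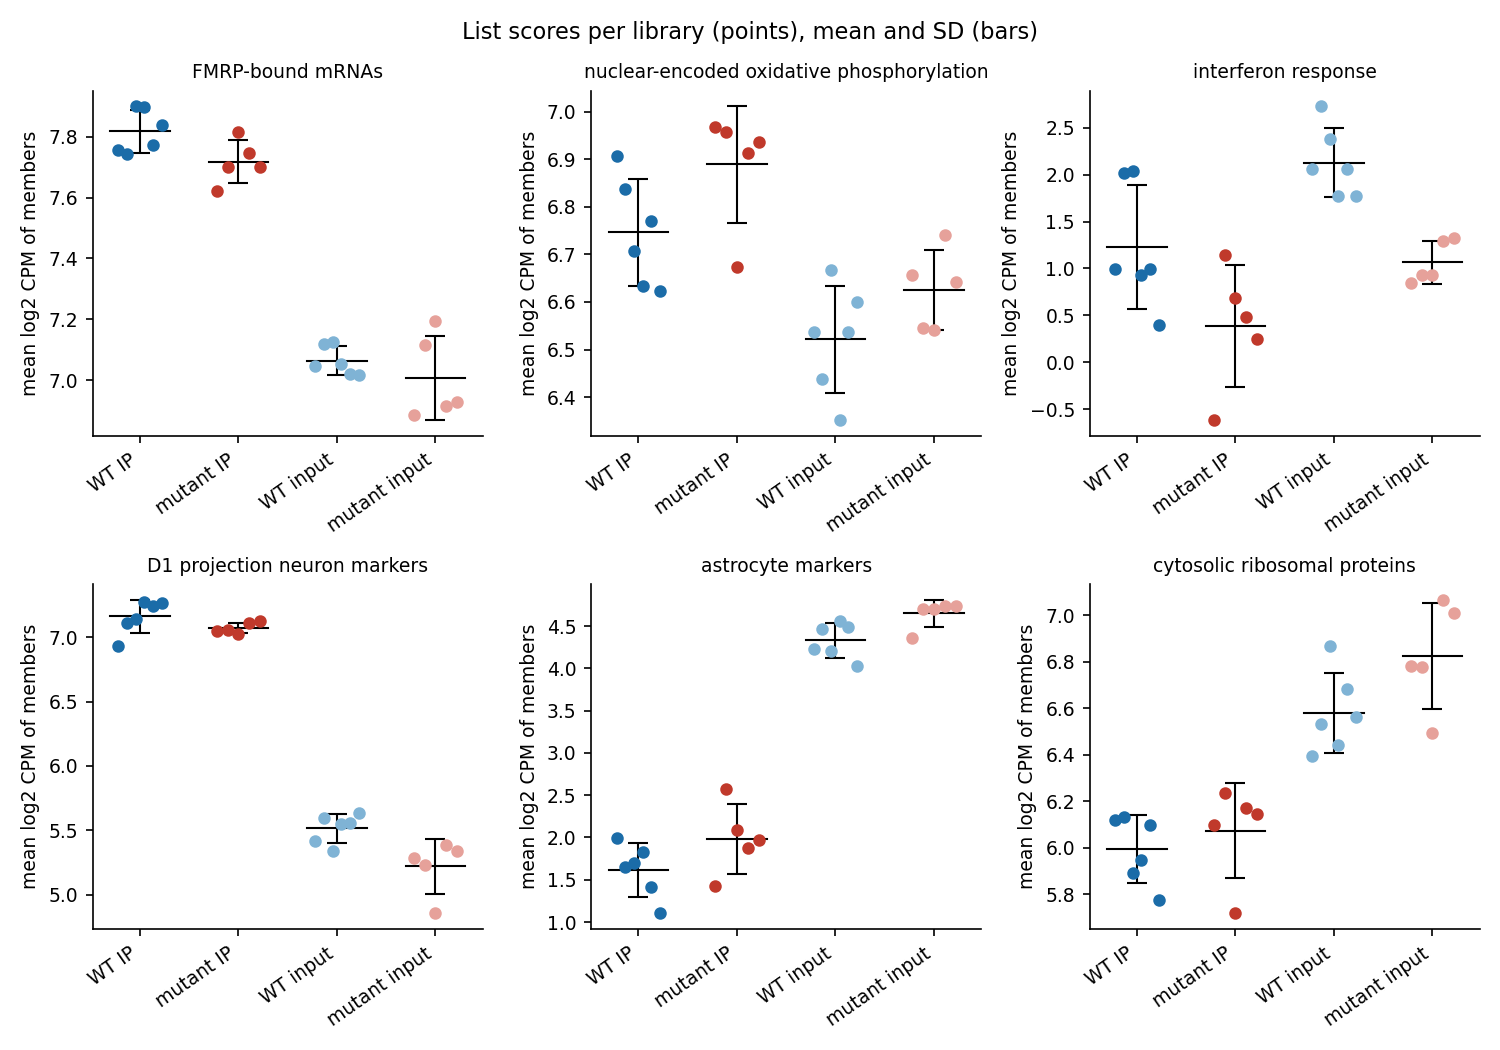
Mean log2 CPM of the members of 6 gene lists in each library (points), with the mean and SD of each group (bars), for wild-type and mutant IP and input. The interferon response score separates the genotypes in input, at 2.13 ± 0.37 in wild type and 1.07 ± 0.23 in the mutant, and the groups overlap in the other panels.

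Mutant and wild type were compared in input, which holds RNA of all striatal cell types. There 3 of 16429 genes tested passed, all lower in the mutant and all called in IP as well. Fmr1 fell by 2.28 ± 0.11 (SE) on the log2 scale. Abi3bp fell from 24.5 CPM ± 3.35 (SD, n = 6) to 8.66 ± 1.25 (SD, n = 5), a log2 change of -1.50 ± 0.14 (adjusted p = 1.45e-05), and Tns1 from 22.8 CPM ± 2.23 to 12.02 ± 2.5, a change of -0.92 ± 0.14 (adjusted p = 0.0179). The next smallest p-values, which did not pass, were those of the photoreceptor cadherin Cdhr1 (-1.79 ± 0.31, adjusted p = 0.0829) and the potassium channel subunit Kcns2 (-0.52 ± 0.10, adjusted p = 0.104). IP and input came from the same lysates, so a gene called in both does not count as independent evidence. Tns1 was not called without animal 3, 4, 10 or 14 (adjusted p up to 0.121, with -1.03 to -0.82 over all leave-outs) or without animals 1, 3, 9 and 12 (-0.81, 0.0596), and the count was 7 without animal 12 and 7 without those 4. The authors' deposited table lists 42 genes at an adjusted p under 0.05, 35 lower and 7 higher in the mutant, with all 3 among them.

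**Figure D5:**
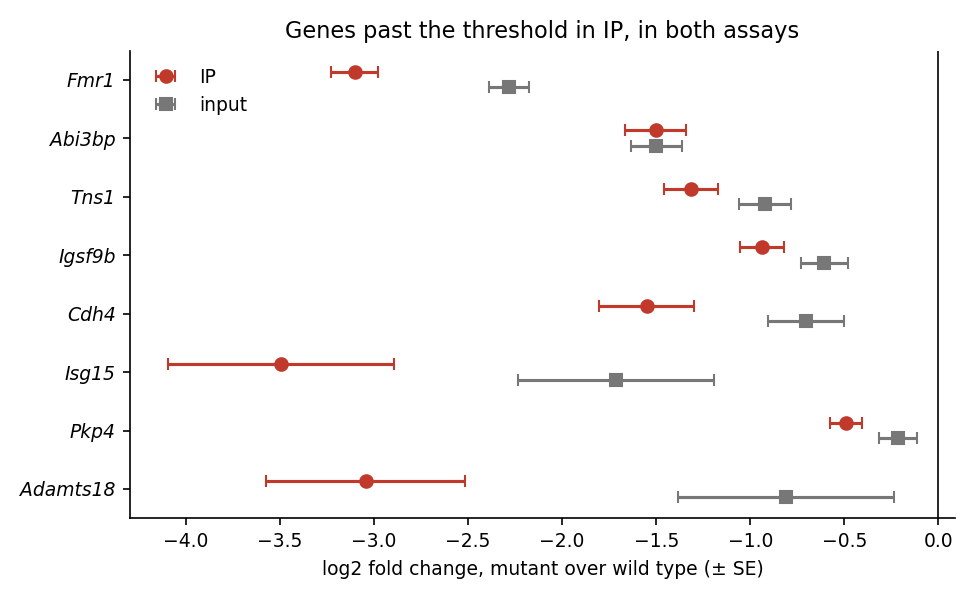
Log2 fold change of mutant over wild type with its SE for the 8 genes called in IP, shown in IP (circles) and input (squares). Fmr1, Abi3bp and Tns1 were also called in input, and the difference between the assays passed for none of the 8.

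The interferon response list was lower in mutant input, and camera called it under every setting used, as did fry (adjusted p = 0.0322). Of 18 members 17 had a negative log2 fold change, with a median of -0.81 (camera adjusted p = 1.10e-18, and adjusted p = 0.0346 with an estimated correlation). None passed over all genes, and 12 fell when adjusted over the list alone. Ifit1, an interferon-induced antiviral protein, changed by -2.73 ± 0.52 (SE), the oligoadenylate synthetase-like gene Oasl2 by -2.59 ± 0.63 and Ifi27 by -0.73 ± 0.20. The list's score was lower in all 5 mutant libraries than in all 6 wild-type libraries (exact permutation p = 0.00216, the smallest possible, and 0.0801 adjusted over the 37 lists scored in input). Microglia markers, a cell type that expresses many of these genes, did not move with it (score difference 0.03 ± 0.13 SE).

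Projection neuron markers were lower and astrocyte markers higher in mutant input. All 10 D1 markers were negative (median -0.27, camera adjusted p = 1.83e-06, and adjusted p = 0.241 with an estimated correlation), with Zfp521 (-0.45 ± 0.10), Slc35d3 (-0.59 ± 0.17) and Drd1 (-0.32 ± 0.12) falling when adjusted over the list alone. All 16 shared projection neuron markers were negative (median -0.18, camera adjusted p = 1.83e-06, and adjusted p = 0.424 with an estimated correlation), and members that fell adjusted over the list alone included Bcl11b, a transcription factor of these neurons (-0.36 ± 0.10), and Actn2 (-0.34 ± 0.11). All 7 D2 markers were negative (median -0.10, camera adjusted p = 0.0440, and adjusted p = 0.378 with an estimated correlation). Of 12 astrocyte markers 11 were positive (median 0.20, camera adjusted p = 0.000134, and adjusted p = 0.255 with an estimated correlation), and Gfap rose by 0.78 ± 0.22 when adjusted over the list alone. Per library, the exact permutation p was 0.0108 for D1, 0.0216 for D2 and 0.0195 for astrocyte markers (0.0938 for each adjusted over the marker lists), and 0.117 for shared projection neuron markers (0.380), whose score differed by -0.19. The shared marker median ranged from -0.25 to -0.09 over the leave-outs and stayed called.

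All 79 cytosolic ribosomal protein mRNAs were positive in mutant input (median 0.24, camera adjusted p = 6.50e-32, and adjusted p = 0.308 with an estimated correlation), and none passed over all genes or adjusted over the list alone. For the next 9 lists, called by camera at its preset correlation, the adjusted p ran from 0.255 to 0.568 with an estimated correlation. Higher were oxidative phosphorylation (66 of 76 positive, median 0.10, adjusted p = 1.53e-08) and oligodendrocyte markers (12 of 14, 0.13, 0.0125). Lower were FMRP-bound mRNAs (127 of 197 negative, -0.05, 0.000431), dopamine and cAMP signalling (24 of 35, -0.09, 0.000829), group I mGluR signalling (15 of 20, -0.11, 0.00309), GABA receptors and synthesis (16 of 20, -0.11, 0.00588), glutamate receptors with postsynaptic scaffolds (29 of 41, -0.10, 0.00637), potassium channels (27 of 43, -0.08, 0.0122) and cholesterol synthesis (18 of 23, -0.12, 0.0274). No member of these 9 lists passed over all genes or adjusted over the list alone. Among lists not called, the cannabinoid receptor Cnr1 (-0.27 ± 0.07) and Rgs4 (-0.46 ± 0.08) fell when adjusted over the list alone. Over all genes Rgs4 did not pass here (adjusted p = 0.104). In the authors' DESeq2 tables its adjusted p is 0.00287 in input and 0.0813 in IP.

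Leaving out animal 2 ended the input calls of FMRP-bound mRNAs (adjusted p = 0.0694, with medians of -0.09 to -0.03 over all leave-outs), group I mGluR signalling (0.0589) and GABA (0.0685), and left 9 lists called. Calls also ended for D2 markers without 2, 4, 9, 12, 13 or 14 (adjusted p up to 0.419, median -0.17 to -0.06) and without animals 1, 3, 9 and 12 (0.423, -0.05), oligodendrocytes without 1, 2 or 11 (up to 0.219, 0.05 to 0.20), glutamate receptors without 2 or 10 (up to 0.0729, -0.12 to -0.05), potassium channels without 2 or 12 (up to 0.376, -0.15 to -0.0046), and cholesterol synthesis without 1, 2, 10, 11 or 12 (up to 0.310, -0.16 to -0.04) and without animals 1, 3, 9 and 12 (0.0856, -0.10 against -0.12). Oxidative phosphorylation (0.07 to 0.14) and dopamine and cAMP signalling (-0.14 to -0.06) stayed called. Without animals 1, 3, 9 and 12 some shifts were larger: FMRP-bound mRNAs (-0.14 against -0.05), glutamate receptors (-0.19 against -0.10) and potassium channels (-0.19 against -0.08). So were those of cytosolic ribosomal proteins (0.42 against 0.24) and oxidative phosphorylation (0.21 against 0.10). Shifts of D1 (-0.24 against -0.27), shared (-0.15 against -0.18) and astrocyte markers (0.18 against 0.20) were smaller.

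The interaction asks whether the genotype difference on ribosomes departs from that in input. Fmr1 had the smallest p. Scaled over all 22 libraries, wild-type Fmr1 stood at 86.3 CPM in IP and 63.7 CPM in input. Mutant Fmr1 stood at 9.99 CPM in IP and 13.2 CPM in input. The log2 ratio of Fmr1 in IP over input was 0.43 ± 0.22 (SD, n = 6) in wild type and -0.40 ± 0.28 (SD, n = 5) in the mutant. Every mutant ratio lay below every wild-type ratio, with a difference of -0.83 (exact permutation p = 0.00216). Over all genes the same difference was -0.83 ± 0.15 (SE) and did not pass (adjusted p = 0.128). The other named genes among the smallest p were Grb14, an insulin receptor adaptor (-0.98 ± 0.21, adjusted p = 0.375), Lgi3 (-1.30 ± 0.29, 0.471) and Prc1 (3.53 ± 0.79, 0.471). Prc1 had 0 to 14 reads in the wild-type IP libraries and 3 to 30 in the mutant ones, so its fold is uncertain. None of 17311 genes passed in edgeR, with 710 at an unadjusted p under 0.05, 0 called by limma-voom and with the animal as a block, and 3 by DESeq2. Without animal 1 or animal 3 the count was 2, and without animals 1, 3, 9 and 12 it was 0.

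Camera called 8 lists in the interaction at its preset correlation, and none with an estimated correlation (smallest adjusted p = 0.949), nor did fry. Cytosolic ribosomal proteins (75 of 79 negative, median -0.18, adjusted p = 1.13e-09), mitochondrially encoded genes (11 of 12, -0.44, 0.000525), microglia markers (10 of 14, -0.41, 0.00489) and FMRP-bound mRNAs (132 of 197, -0.05, 0.0130) were lower in IP relative to input in the mutant. D1 markers (8 of 10 positive, 0.18, 0.0130), shared projection neuron markers (14 of 16, 0.10, 0.0130), interneuron markers (10 of 13, 0.57, 0.0185) and D2 markers (7 of 7, 0.27, 0.0465) were higher. The microglia genes Cx3cr1 (-2.73 ± 0.78) and Trem2 (-2.69 ± 0.89) fell when adjusted over the list alone, and no member of the other 7 lists did. Only 7 microglia and 9 interneuron markers passed the filter in the fit of IP libraries alone. Their mean log2 CPM there was 0.11 in wild type and -0.34 in the mutant for microglia, and -0.16 and 0.21 for interneurons. Both calls thus rest in part on IP counts near the floor. With the animal as a block the calls of D2 markers (0.0526) and interneurons (0.119) ended and dopamine and cAMP signalling was called (0.0258). Leaving out single animals ended all but the cytosolic ribosomal protein (medians from -0.27 to -0.10) and mitochondrially encoded calls (-0.52 to -0.23, adjusted p up to 0.0423): FMRP-bound mRNAs without 3, 9, 13, 14 or 20 (adjusted p up to 0.775), D1 (up to 0.262) and shared markers (up to 0.519) without 4 or 9, D2 (up to 0.374) and interneurons (up to 0.856) without 3, 4, 9, 10, 14 or 20, and microglia without 2 or 10 (up to 0.1065). The number of lists called was 4 without animal 9 and 5 without animal 3, 14 or 20. Without animals 1, 3, 9 and 12 together, the calls of FMRP-bound mRNAs (0.01, adjusted p = 0.908), D1 (0.10, 0.576), D2 (0.02, 0.576), shared (0.04, 0.200) and interneuron markers (0.23, 0.889) ended.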

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

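Chosen after the results were seen were the tests of microglia content and of single libraries for the interferon response, of glial and vascular markers moving alike, of cortical tissue for D1 and D2 markers, the counts of divisions without Fmr1, and all settings without animals 1, 3, 9 and 12.

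Camera at its preset correlation called FMRP-bound mRNAs lower and oxidative phosphorylation mRNAs higher in mutant IP (adjusted p = 0.441 and 0.462 with an estimated correlation). The FMRP-bound genes are long, with a median exon length of 11053 bases against 4288 over all genes, so a trend with length was tested: among 10000 random lists matched on exon length, GC content and expression, the medians lay at percentile 0 (95% of random medians from -0.08 to -0.04) and percentile 100 (from 0.02 to 0.08), while the matched lists shifted the same way as each list. That bound was wrong as a test, since random lists hold only the spread between genes and not that between animals, and when each list's score was taken relative to its matched genes per animal, the difference was -0.03 ± 0.04 (SE, exact permutation p = 0.452) for FMRP-bound mRNAs and 0.09 ± 0.04 (exact permutation p = 0.0714) for oxidative phosphorylation. Cortical tissue in animals 1, 3, 9 and 12 is argued against as the whole cause, since without them the medians were -0.14 and 0.20. A trend with length, GC content and expression cannot be told apart from a change of the lists, since 11 animals leave the relative scores uncertain, chance differences between animals could account for what remains, and an effect of the genotype stays open.

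Interferon response mRNAs were lower in mutant input. Fewer microglia are argued against, since the microglia score differed by 0.0275 ± 0.135 (SE) while the interferon score fell by 1.06 ± 0.18 on the log2 scale. A single library is argued against, since the score difference was -1.13 to -0.94 over the 11 leave-outs (-0.942 ± 0.152 SE nearest to 0), and without animals 1, 3, 9 and 12 it was -0.93 ± 0.27 (SE). A shared litter, cage or infection in part of the animals could give such a pattern and stays open, as the labels name none, and so does an effect of the genotype.

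Camera at its preset correlation called D1, shared and D2 projection neuron markers lower in mutant input (adjusted p = 0.241, 0.424 and 0.378 with an estimated correlation). Cortical tissue in 4 animals is argued against as the whole cause for D1 and shared markers, since without them both lists were still called and the scores differed by -0.25 ± 0.03 (SE) and -0.11 ± 0.03, against -0.30 and -0.19 ± 0.11 with all animals (exact permutation p = 0.0108 and 0.117). For D2 markers it stays open, since without them the score differed by -0.12 ± 0.05 (SE) against -0.18, but the list's median moved from -0.10 to -0.05 and its call ended (adjusted p = 0.423). The D2 call also ended with the cortical score as a covariate, and with all 22 libraries in a single fit. A lower share of neurons with all other cell types raised alike stays open: the differences of astrocyte and endothelial scores lay 0.467 ± 0.200 (SE) apart, but these were picked as the highest and lowest of 4, and the endothelial score lies near the floor (0.27 in wild type and 0.13 in the mutant). Astrocyte content alone and the genotype stay open, and the dissection may still differ between animals.

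A sample far from the rest of its group was found in 18 of 182 groups of values, where chance gives 9.1. In mutant IP, animal 9 was lowest in the scores of cytosolic ribosomal proteins (5.72), mitochondrial ribosomal proteins (4.46) and oxidative phosphorylation (6.67), and animal 2 in that of immediate early genes (4.18). In mutant input, animal 9 was lowest in D1 markers (4.85) and D2 markers (5.18), and animal 2 was lowest in astrocyte markers (4.36) and immediate early genes (3.01) and highest in dopamine and cAMP signalling (6.70). In wild-type input, animal 12 was lowest in shared projection neuron markers (8.36) and highest in potassium channels (5.18), animal 20 was highest in ependyma and choroid plexus (3.54) and oligodendrocyte precursors (3.23), animal 4 was highest in group I mGluR signalling (6.89), and animal 1 was lowest in red blood cell markers (1.38). In wild-type IP, animal 12 was highest in endocannabinoids (5.07). Mutant animal 10 stood apart for Igsf9b in IP (41.96 CPM, the others 30.6 to 33.6) and for Cdhr1 in input (1.72 CPM, the others 0.749 to 0.977).

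Camera at its preset correlation called 8 lists in the interaction of genotype and assay, with adjusted p of 1.13e-09 for cytosolic ribosomal proteins, 0.000525 for mitochondrially encoded genes, 0.00489 for microglia, 0.0130 for FMRP-bound mRNAs, D1 markers and shared projection neuron markers, 0.0185 for interneurons and 0.0465 for D2 markers. With an estimated correlation none was called (smallest adjusted p = 0.949), nor by fry. The ratio of Fmr1 in IP over input differed between genotypes by -0.83 (log2).

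Other divisions of the samples were counted, 100 per comparison with the real one included. For genes, chance is argued against in IP (1 of 100 as large, 8 called against at most 4 in other divisions, and 1 of 100 with Fmr1 left out, 7 against 4) and for IP against input in wild type (1 of 100, 8585 against at most 3459) and the mutant (1 of 100, 8188 against at most 1880), and not for the interaction, where all 100 gave at least the real count of 0 (highest other 3). In input 4 of 100 gave as many genes (3 called against at most 29), but with Fmr1, whose mutation defines the groups, left out, 6 of 100 did (2 against 29), so chance stays open for the other 2 genes by this count. The input division that called 29 genes differed from the real one only by exchanging wild-type animal 12 for mutant animal 9, and points to a structure of the samples, the nature of which was not tested. Among divisions that part every IP library from its own input, the highest count was 978 over 8 others in wild type and 1 over 12 others in the mutant. For the number of lists called, chance stays open in IP (16 of 100 as large, 14 called, highest other 19), input (14 of 100; 15, 19) and the interaction (24 of 100; 8, 17). For IP against input the count of lists, at 40 of 100 in wild type (23, 29) and 24 of 100 in the mutant (23, 26), does not exclude chance either, but other divisions called a median of 21 and 17 lists, so this count tells little, and 12 and 10 lists kept their calls with an estimated correlation.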

How the results depend on the processing

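Settings that leave out animals 1, 3, 9 and 12 or use a cortical score were chosen after the data were seen. Genes called in IP numbered 83 with DESeq2, 4 with limma-voom, 13 with all 22 libraries in a single fit and 5 with the glial and vascular score, against 8, and 4 to 8 without single animals. In input they numbered 54 with DESeq2, 5 without a filter beyond 1 read, 6 with all 22 libraries, 9 with a surrogate variable and 7 without animals 1, 3, 9 and 12, against 3, and 2 to 7 without single animals. In the interaction DESeq2 called 3 against 0, and 0 to 2 were called without single animals. Lists called by camera with an estimated correlation were 0 in IP, 1 in input, 12 and 10 for IP against input in wild type and mutant, and 0 in the interaction. Fry called 0 in IP, 1 in input, 33 and 30 for IP against input in wild type and mutant, and 0 in the interaction. Without single animals, lists called ranged from 9 to 16 in IP, 9 to 19 in input and 4 to 10 in the interaction (23 to 25 and 23 to 24 for IP against input in wild type and mutant, with 7661 to 8923 and 7345 to 8325 genes), which had 4 without animals 1, 3, 9 and 12. The direction given by camera reversed in 3 cases, counted only where a list was called in the main fit or under the alternative. Synaptic vesicle release in input had medians of -0.069 without animal 9 (camera adjusted p = 0.0243) and -0.080 without animals 1, 3, 9 and 12. Its main median was 0.02, and it reached 0.092 without animal 11. The third case was FMRP-bound mRNAs in the interaction, with a median of 0.0080 without animals 1, 3, 9 and 12. The cause of these differences was not tested, except that leaving out animals leaves fewer samples. Paired by animal as a replicate block, 9319 genes were called for IP against input in wild type and 8906 in the mutant, and the block changed no call of a list other than those given with the results. Fmr1, Abi3bp, Tns1 and Igsf9b kept their calls in IP in all 21 alternatives, with a highest adjusted p of 0.0386. Of list values under all alternatives, 3159 kept their call or lack of it, 196 lost a call and 127 gained one. Depth limits genes such as Isg15 and Adamts18 in IP, with 1 to 17 and 2 to 6 reads in the mutant libraries.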

Other observations

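No test in this part was chosen after the results were seen.

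Immediate early genes, which neuronal activity induces, lay higher in mutant IP in 12 of 19 members (median 0.19) without being called (camera adjusted p = 0.327). Animal 2 was the lowest mutant in this score, so leaving it out raises the difference by construction. Without animal 2 camera at its preset correlation called the list higher in the mutant in IP (median 0.38, adjusted p = 3.72e-05). The same held in input (median 0.18, camera adjusted p = 0.00739). These 2 calls are thus no evidence of a higher level in the mutant. They were not tested with an estimated correlation or fry. The activity-dependent transcription factor Npas4 stood at 1.24 ± 0.60 (SE) and Junb at 0.39 ± 0.23. The score gave an exact permutation p of 0.506 in IP and 0.532 in input.

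Regulators of G-protein signalling were lower in 10 of 15 members in mutant IP (median -0.10, camera adjusted p = 0.0527) and in 12 of 16 in input (-0.06, 0.0605), and the list was not called in either. The list of FMRP family and partners, which holds the paralogs Fxr1 and Fxr2, had medians of -0.03 in IP (camera adjusted p = 0.359) and -0.05 in input (0.213). Translation factors had medians of 0.02 (0.310) and 0.03 (0.437), and the mTOR pathway -0.06 (0.215) and -0.03 (0.621). No member of the latter 3 lists passed over all genes, and adjusted over the list alone Eif1 rose in IP (0.26 ± 0.06 SE).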
